A study of Mus musculus with 6 samples.

How the data were processed

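Cells of 6 libraries were sorted for CD45 from dissociated mouse melanomas and prepared with the 10x Genomics Next GEM single-cell 3' v3.1 chemistry, per the labels. The deposited values are counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized, in filtered matrices of 32285 features. The submitters' processing notes name mm10, Cell Ranger 6.0.1 and Seurat 4.1.1 without their roles, and neither the annotation release nor the use of strand is given in the sources used here. Coordinates are from GENCODE M21 on GRCm38, the assembly of mm10, and 32158 of the 32285 feature identifiers matched it. Each genotype label, Arf6null or Arf6wt, came from the sample titles and characteristics. Replicate numbers only follow the order of the records, so they pair no samples. The titles open with 3 prefixes, of which 19203 holds Arf6null replicates 1 and 2, 19255 holds Arf6wt replicate 3, and 19237 holds Arf6null replicate 3 with Arf6wt replicates 1 and 2.

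The libraries held 95481538, 92984472 and 70699810 UMIs in Arf6null replicates 1 to 3 and 53880457, 29489535 and 98621362 UMIs in Arf6wt replicates 1 to 3. Pairs of libraries differed by a chi-square of 131 to 1062 per degree of freedom and shared 0.158 to 0.484% of their barcodes, so each was counted as its own sample. A barcode was retained with at least 500 UMIs and 200 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet, as scanpy runs it, and the cells of highest score were removed, 0.8% of them per 1000 barcodes, which came to 5.05 to 8.96% of the cells. Cells were log-normalised and reduced to 2000 variable genes (leaving out immune receptor, mitochondrial, ribosomal, haemoglobin and sex-linked genes) and 30 principal components, then clustered with 15 neighbours and the Leiden method at resolution 1, without integration of the libraries. T and NK clusters were clustered again the same way. Clusters were named from 24 marker lists, and a cluster whose leading genes went against a name, or with fewer than 3 detected markers, stayed unnamed. So did a cluster with median UMIs under 0.333 of its library's and no marker among its 10 leading genes. A cluster best matched by a non-immune list stayed unnamed with fewer than 2 of its markers there, and so did T cells neither CD4 nor CD8. The marker lists were fixed before the data were examined and the scoring rule after.

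Counts were summed per library and cell class and tested with edgeR's quasi-likelihood test (filterByExpr, TMM), with Benjamini-Hochberg adjustment at 0.05. A library with fewer than 20 cells of a class was left out of it, and a class was tested with at least 2 libraries per genotype. Levels in CPM are normalised by TMM, except those of single libraries for Arf6 and the genes 10-fold apart, of the Ptprc-low cells' Arf6 and marker genes and of regulatory T-like cells, which are UMIs of the gene over all UMIs of the summed cells, as CPM without TMM. The 23 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. For 3 of their symbols no feature carried the name. Where the libraries of a genotype hold 0 UMIs, a fold is a lower bound from a floor of 3 counts over the group, and no bound is read from a fitted fold. Floors and intervals (95%) cover counting error only. Shares of cells were tested with edgeR on cell counts with the retained cells as library size, and with exact two-sided permutation tests.

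Genes are named by a fixed rule. In each class these are the genes past the threshold with all libraries of one genotype above the other and at least 10 CPM in the higher one, up to 10 each way. Receptor segments, sex-linked genes, haemoglobin genes and models named Gm or Rik were left out of that ranking: 3 of them passed in all cells, 4 in CD8 T-like, 1 each in CD4 T-like, NK-like, macrophage- or monocyte-like and dendritic-like, and 0 in neutrophil-like cells. Where fewer than 5 genes passed, the 5 of smallest p are candidates for naming, as are up to 4 members of each list and a fixed set of T cell and macrophage genes, not all of which are reported here. The gene lists, markers, filters, tests and this rule were chosen before the data were examined. The tests of the Ptprc-low cluster, and the features that the text names outside the rule, were chosen after their values were seen.

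The alternatives were DESeq2 (Wald test), DESeq2 size factors in edgeR, no filter on low counts, the title prefix as a covariate, a stricter cell filter (1000 UMIs, 5% mitochondrial), doublets kept, Leiden resolution 2, an estimated correlation and each library left out. The presence of Y-linked reads as a covariate and the MHC class II list without H2-Eb1 were chosen after seeing the data. On simulated counts with 200 changed genes, 4-fold changes were recovered for 57% of genes over all cells (15454 genes tested), 85% in CD8 T-like (8936), 76% in CD4 T-like (2309), 75% in NK-like (7413), 73% in macrophage- or monocyte-like (13645), 44% in dendritic-like (8583), 76% in neutrophil-like (7891) and 60% in Ptprc-low cells (11350), and 32-fold changes for 100% in each. Each gene was given the typical spread between libraries for its level, without the differences in spread between genes, so real recovery can be lower. In the Ptprc-low cells Esm1, at a fitted log2 change of 11.7, did not pass in edgeR (adjusted p = 0.0576). The simulated sets also gave 1 to 16 false calls each. For shares, 16-fold changes were recovered in 24% of 100 simulations. Versions were Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-image 0.26.0, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.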

Results

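Single-cell transcriptomes were collected from CD45+ cells sorted out of dissociated mouse melanomas. All tumours carried a Cre-activated Braf allele and floxed Cdkn2a, a tumour suppressor locus. The Arf6null tumours also carried floxed Arf6, which encodes a small GTPase of endosomal traffic. There were 3 Arf6null and 3 Arf6wt libraries, and the study's title places the loss of Arf6 in the tumour cells and asks what it does to the immune cells around them. The libraries held 29489535 to 98621362 unique molecular identifiers (UMIs) over 6328 to 11205 cell barcodes, and 5354 to 9357 cells per library were retained. The median depth of retained cells was 4975, 8634 and 6490.0 UMIs in Arf6null replicates 1 to 3 and 5013.5, 3363 and 12924 UMIs in Arf6wt replicates 1 to 3. The design text speaks of 3 tumours per genotype and the titles carry separate numbers. Separate animals are not stated, so p-values measure the spread between these samples. The sex of the animals is not given either. Reads of the Y-linked gene Ddx3y came almost only from Arf6null replicates 2 and 3, and the Arf6wt libraries held 0. Sex therefore appears partly confounded with genotype in every comparison. Levels are means ± SD over libraries in counts-per-million (CPM), and log2 changes are Arf6null over Arf6wt with their SE. That SE is the absolute log2 change over the square root of the test's F statistic, not a value fitted by the model. For genes near the floor in a genotype it is rough. Cell classes, named from marker genes, are written as X-like.

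Arf6 was almost absent from a cluster of Ptprc-low cells in the Arf6null tumours, whereas in the immune classes described here its levels overlapped between genotypes. Arf6 (ENSMUSG00000044147) lies on mm10 chromosome 12 at 69372150 to 69373783, plus strand, with a coding region at 69372794 to 69373318 inside exon 2. Which part was floxed is not given in the sources used here, and the 3' tags read the end of the transcript, so a tag outside the deleted part would check nothing. Over all retained cells Arf6 was at 56.9, 51.8 and 94.2 CPM in the Arf6null libraries and 111, 87.3 and 65.8 CPM in the Arf6wt libraries. These values overlapped (log2 change −0.51 ± 0.32, edgeR quasi-likelihood test, adjusted p = 0.513). An exact two-sided permutation test gave p = 0.3, where 0.1 is the smallest p that 3 against 3 libraries allow. Within the title prefix 19237, the only one holding both genotypes, TMM-normalised Arf6 was at 85.9 against 117 and 98.2 CPM, a difference of −0.32 on the log2 scale. Macrophage- or monocyte-like cells held 70.6 ± 24.5 against 90.4 ± 27.8 CPM (exact p = 0.5). Arf6 was at 93.0 ± 36.3 against 90.5 ± 7.54 CPM in neutrophil-like cells (exact p = 0.9) and at 113 ± 43.1 against 105 ± 25.7 CPM in CD8 T-like cells (exact p = 0.8).

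A single unnamed cluster had the lowest level of Ptprc, the gene of CD45, at 11.1 CPM. It was examined after the data were seen because the sort should hold few cells of that kind. It was led by Clu, Apod, Tm4sf1, Crabp1, Hmga2, Prrx1 and Krt8, and held 100, 237 and 219 cells of the Arf6null and 61, 93 and 317 cells of the Arf6wt libraries. At Leiden resolution 2 the cluster with these leading genes scored highest for the fibroblast list. It had 8 of those markers detected but 0 among its 10 leading genes, so the list gave no name. Arf6 was at 0.856, 1.01 and 1.28 CPM in the Arf6null libraries (4, 7 and 8 UMIs) and at 104.9, 79.6 and 62.0 CPM in the Arf6wt libraries (243, 154 and 823 UMIs). The means of 1.05 ± 0.216 and 82.2 ± 21.6 CPM differed 78.2-fold, and Arf6 fell by 6.26 ± 0.38 on the log2 scale (edgeR, adjusted p = 0.00101; exact p = 0.1). The call ended with the title prefix or the presence of Y-linked reads as a covariate, with an adjusted p of up to 0.238, while the fitted change stayed between −6.52 and −6.01 over 11 alternatives. The pigment cell markers Pmel (0.346 against 0.589 CPM), Mlana (0 UMIs) and Sox10 (0 UMIs) were near or at the floor in both genotypes. Mitf, the melanocyte transcription factor, was at 8.89 against 16.5 CPM. The neural crest factor Foxd3 was at 30.9 ± 19.2 against 6.48 ± 1.46 CPM.

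**Figure D1:**
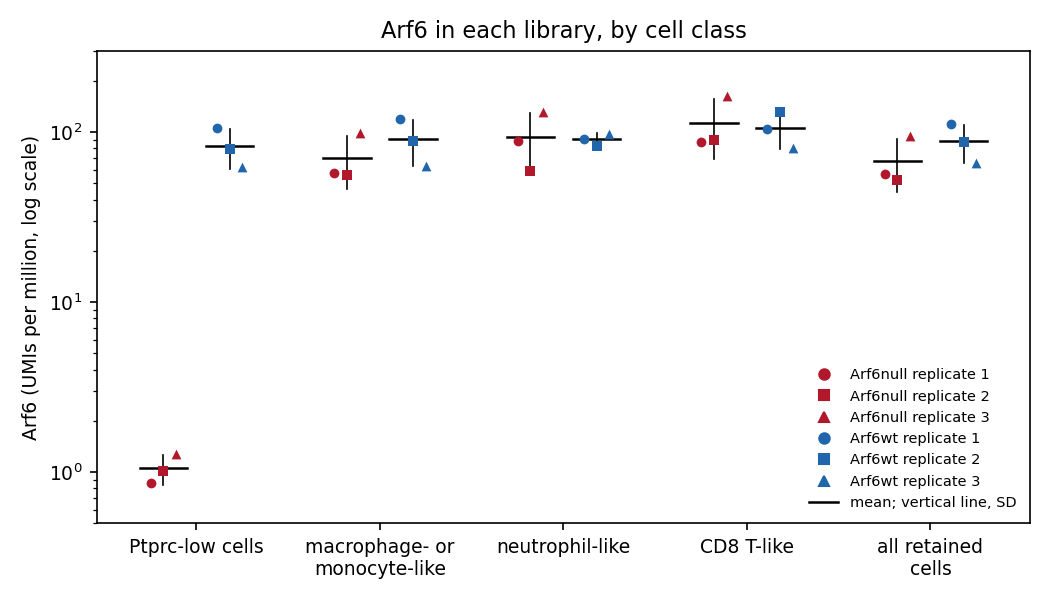
Arf6 in each library in CPM of UMIs on a log scale, by cell class; points are libraries, horizontal bars group means and vertical lines the SD. The Arf6null points lie at 0.856 to 1.28 CPM in the Ptprc-low cells against 62.0 to 104.9 CPM for Arf6wt, and the groups overlap in the 4 other sets of cells.

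Within these Ptprc-low cells 6 of 11604 tested genes passed, 1 higher and 5 lower in Arf6null, and 712 had an unadjusted p under 0.05. Besides Arf6, the lower genes were Pdpn, which encodes the membrane glycoprotein podoplanin (0.193 against 104 ± 74.2 CPM, adjusted p = 0.0102), and Cda, a cytidine deaminase (0 against 52.4 CPM, at least 264-fold lower, adjusted p = 0.0152). The uncertain features BC023719 and Gm10260 were lower too (both adjusted p = 0.0102). H2-Eb1, an MHC class II beta chain, was higher at 71.9 ± 26.6 against 0.578 CPM (adjusted p = 0.0136). Cda, BC023719, Gm10260 and H2-Eb1 are among 14 genes 10-fold apart over all cells, for which a difference in strain background stays open. In the Ptprc-low cells the myeloid gene Lyz2 was at 134 ± 101 against 26.4 ± 19.6 CPM (exact p = 0.3) and Ptprc at 14.4 ± 6.26 against 9.52 ± 3.45 CPM (exact p = 0.2). Proliferation genes were higher as a list, with 25 of 25 members positive, 0 passing over all genes and 5 passing when adjusted over the list alone. Camera gave an adjusted p of 4.86e-16 (and adjusted p = 0.431 with an estimated correlation). The ARF family and endomembrane list was lower with 19 of 25 members negative, of which Arf6 alone passed (camera, adjusted p = 0.00358, and adjusted p = 0.294 with an estimated correlation). Without Arf6null replicate 2 the count of genes was 11, and without Arf6null replicate 3 it was 1. In the latter Pdpn, Cda, H2-Eb1, BC023719 and Gm10260 had adjusted p-values of 0.0721 to 0.121. H2-Eb1 and Gm10260 also lost their calls without Arf6null replicate 1 (adjusted p of 0.0517 to 0.0607), and H2-Eb1 without Arf6wt replicate 2 (adjusted p = 0.0991). Arf6 kept its call without any single library. All 6 calls ended with the title prefix (adjusted p of 0.103 to 0.722) or Y-linked reads (0.238 to 0.365) as a covariate.

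Counts were also summed per library over all retained cells of the CD45+ sort, the Ptprc-low and other unnamed cells among them. There 21 of 15709 genes differed, 11 higher and 10 lower in Arf6null (edgeR quasi-likelihood, adjusted p under 0.05), and 2238 had an unadjusted p under 0.05. The groups stood apart for 19.7% of genes, where chance gives 10%. Ifi44l, an interferon-inducible gene, rose to 59.4 ± 52.9 from 0.0468 ± 0.0339 CPM (log2 change 10.51 ± 0.97, adjusted p = 0.0183). Its neighbour Ifi44 rose to 88.1 ± 49.0 from 5.31 ± 2.23 CPM (4.05 ± 0.50, adjusted p = 0.0479). Folr2, a folate receptor of tissue-resident macrophages, rose to 72.2 ± 33.4 from 7.21 ± 0.704 CPM (3.32 ± 0.39, adjusted p = 0.0434). H2-Eb1 rose to 3576 ± 1980.4 from 42.6 ± 5.86 CPM (6.39 ± 0.58, adjusted p = 0.0183). Apol7c, an apolipoprotein L gene, was at 27.5 ± 2.78 against 0.0842 ± 0.0727 CPM (adjusted p = 0.0176). Cd200r4, a CD200 receptor family gene, was at 11.4 ± 2.42 against 1.91 ± 0.175 CPM (adjusted p = 0.0434). The mitochondrial asparaginyl-tRNA synthetase Nars2 fell to 5.48 ± 1.47 from 29.6 ± 5.50 CPM (−2.43 ± 0.30, adjusted p = 0.0473). Vill, a villin-like gene, fell to 0.0274 from 18.6 ± 11.4 CPM (−9.37 ± 0.78, adjusted p = 0.0176), and BC023719, annotated as antisense within the MHC, to 0.0188 ± 0.0164 from 26.8 ± 6.97 CPM (−10.43 ± 0.68, adjusted p = 0.0102). Within the shared prefix the log2 differences were 10.59 for Ifi44l, 4.65 for Ifi44, 2.47 for Folr2, 6.996 for H2-Eb1 and −2.71 for Nars2. The count was 10 without Arf6null replicate 1, 4 without Arf6null replicate 2, Arf6null replicate 3 or Arf6wt replicate 1, and 3 without Arf6wt replicate 2. Of these 9 genes BC023719 alone kept its call without any single library, and leaving out any of the 6 libraries ended 5 to 7 of the 8 other calls, at adjusted p-values of 0.0512 to 0.275. The title prefix as a covariate ended the calls of Ifi44, Folr2, Cd200r4, Nars2, Vill and BC023719 (adjusted p of 0.252 to 0.310), and Y-linked reads as a covariate ended all 9 (0.0801 to 0.380). The stricter cell filter ended those of Ifi44, Cd200r4 and Nars2 (adjusted p = 0.0517), and keeping doublets that of Nars2 (0.0607).

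Of the 21 called genes 11 stood at least 10-fold apart between all libraries of the genotypes, among them Ifi44l, H2-Eb1, Apol7c, Vill and BC023719. With a 10-fold gap between the groups and at least 2 CPM in each library of the higher genotype, a rule set after the data were seen, there were 14 such genes on 9 chromosomes. Of these 6 were higher in Arf6null and 8 in Arf6wt, with 0 on chromosome 12, which holds Arf6. H2-Eb1 (chromosome 17, 34305867 to 34316674) was at 2699.7, 2196 and 6419.8 against 44.4, 39.8 and 38.9 CPM. BC023719 (chromosome 17, 36111426 to 36117121) was at 0, 0.0252 and 0.0327 against 28.8, 27.7 and 20.3 CPM. Cstdc5, of the stefin cluster of cathepsin inhibitors on chromosome 16, was at 0.0925, 11.6 and 0.0163 against 504, 832 and 241 CPM, and its neighbours Cstdc6, Stfa2 and Stfa3 had the same direction. The H2, Skint, Apol7 and stefin genes belong to multigene families and BC023719 overlaps MHC genes on the other strand. Reads may be split or shared there, and these features are uncertain. Other divisions of the libraries into 3 and 3 gave a median of 0 and at most 7 such genes. Divisions of other sizes gave up to 16, for Arf6null replicates 1 and 3 against the rest, and 12 for Arf6wt replicate 3 alone.

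**Figure D2:**
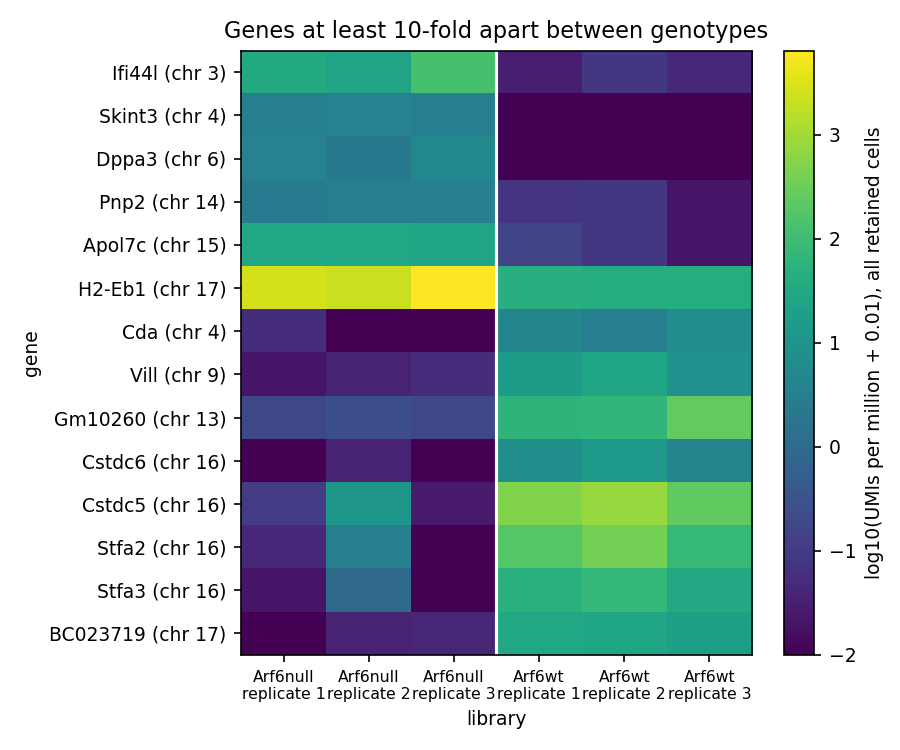
Level of 14 genes in each library over all retained cells, as log10 of CPM plus 0.01 (colour); columns are libraries, with Arf6null left of the white line, and the chromosome stands beside each gene. The upper 6 genes are higher in the Arf6null libraries and the lower 8 in the Arf6wt libraries.

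Of 23 gene lists fixed before the data were examined, 7 passed over all retained cells. Of the 10 splits of the libraries into 3 and 3, 7 gave at least as many lists, the real one among them. The highest other split gave 11, so the number of lists does not set genotype apart from other groupings. Proliferation genes were higher as a list, with 23 of 25 members positive, 0 passing over all genes (edgeR, 18 at an unadjusted p under 0.05) and 17 passing when adjusted over the list alone. Camera gave an adjusted p of 3.58e-18 (and adjusted p = 0.466 with an estimated correlation). Among them Top2a, the mitotic topoisomerase, was at 58.9 ± 6.04 against 20.03 ± 2.80 CPM and Nusap1, a spindle protein gene, at 13.3 against 4.12 CPM. NF-kB response genes were lower as a list, with 17 of 17 members negative, 0 passing over all genes (7 at an unadjusted p under 0.05) and 3 passing when adjusted over the list alone (adjusted p = 2.01e-07, and 0.679 as the adjusted p with an estimated correlation). The adhesion molecule gene Icam1 was at 93.6 ± 28.3 against 279.6 ± 115 CPM and the superoxide dismutase gene Sod2 at 143 ± 24.7 against 427 ± 248 CPM. Proinflammatory macrophage genes were lower as a list, with 12 of 18 members negative and 3 passing when adjusted over the list alone (adjusted p = 0.00742, and adjusted p = 0.619 with an estimated correlation). Among them the cytokine gene Il1a was at 82.4 ± 8.26 against 351 ± 251 CPM and Acod1, which makes itaconate, at 23.3 against 255 CPM.

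Immediate early genes were lower in 17 of 18 members (adjusted p = 0.00742, and adjusted p = 0.679 with an estimated correlation), and stem-like or memory T cell genes in 11 of 13 (adjusted p = 0.0374, and adjusted p = 0.619 with an estimated correlation). The full name of the immediate early list is dissociation and immediate early response. Whether tissue dissociation set it, here or in the cell classes below, was not tested. Oxidative phosphorylation genes were higher in 24 of 24 (adjusted p = 0.0274, and adjusted p = 0.616 with an estimated correlation). MHC class II genes were higher in 12 of 14, of which H2-Eb1 alone passed (adjusted p = 0.00129, and adjusted p = 0.679 with an estimated correlation). For the list MHC class II presentation in all retained cells the call ended without H2-Eb1 (adjusted p = 0.0904). None of the 7 calls held with an estimated correlation. Marker lists of macrophages and mature dendritic cells were also higher and those of neutrophils and monocytes lower over all cells (camera, adjusted p = 7.03e-05, 0.000268, 7.03e-05 and 0.0236, each 0.751 with an estimated correlation). These sums mix the make-up of the tissue with expression. The immediate early call ended without Arf6null replicate 1, Arf6null replicate 2 or Arf6wt replicate 2, and the stem-like call without Arf6null replicate 2, Arf6null replicate 3 or Arf6wt replicate 1. The proinflammatory call ended without Arf6null replicate 2 and the oxidative phosphorylation call without Arf6null replicate 2 or Arf6wt replicate 2. The adjusted p-values there were 0.066 to 0.332. The title prefix as a covariate ended the proinflammatory, oxidative phosphorylation and immediate early calls (adjusted p of 0.0731 to 0.141). Y-linked reads as a covariate ended the oxidative phosphorylation and stem-like calls (0.0985 to 0.155), and the stricter cell filter also ended the oxidative phosphorylation call (0.0585). The other 16 lists did not pass, with hypoxia nearest at 0.058 and the interferon gamma response at 0.805.

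CD8 T-like cells of the Arf6null tumours held more transcripts of exhaustion-associated genes and fewer of stem-like genes as lists. Neither call held with an estimated correlation (adjusted p = 0.226 and adjusted p = 0.277 with an estimated correlation), and 0 exhaustion genes passed over all genes (edgeR), 8 of them when adjusted over the list alone. The granzyme gene Gzmk rose to 156 ± 53.7 from 4.04 ± 4.19 CPM (log2 change 4.89 ± 0.51, adjusted p = 0.00141). It was at 128, 122 and 218 CPM in the Arf6null libraries and 8.36, 0 and 3.75 CPM in the Arf6wt libraries. Wls, the carrier of secreted Wnt proteins, rose to 272 ± 73.3 from 29.3 ± 5.33 CPM (3.25 ± 0.36, adjusted p = 0.00168). The epidermal growth factor receptor ligand Areg rose to 42.0 ± 10.98 from 3.61 ± 2.25 CPM (3.56 ± 0.51, adjusted p = 0.0117) and Adgrg1, an adhesion receptor of cytotoxic lymphocytes, to 39.4 ± 11.8 from 4.16 ± 1.60 CPM (3.06 ± 0.42, adjusted p = 0.0101). Sv2c, a vesicle glycoprotein gene, was at 29.1 ± 18.9 against 0.502 CPM (adjusted p = 0.0173) and the integrin gene Itgb8 at 10.1 ± 4.24 against 0.189 CPM (adjusted p = 0.0144). H2-Eb1 was at 76.5 ± 10.97 against 2.10 ± 1.08 CPM (adjusted p = 0.00036). This may be RNA from other cells, so the H2-Eb1 call need not be a change in T cells. In the Arf6null libraries its level was 1.23 to 2.49% of that in macrophage- or monocyte-like cells. For H2-Aa, H2-Ab1 and Cd74 the median was 1.02 to 2.13%. BC023719 (at least 60.1-fold lower, adjusted p = 0.00119) and the uncertain MHC family gene H2-T3 (0 against 23.3 ± 14.7 CPM, adjusted p = 0.0101) were lower in Arf6null. Within the shared prefix the log2 differences were 6.26 for Gzmk, 3.17 for Wls, 3.32 for Areg and 3.68 for Adgrg1.

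In total 13 of 9215 genes passed in CD8 T-like cells, 8 higher and 5 lower, with 673 at an unadjusted p under 0.05 and the groups apart for 11.2% of genes, where chance gives 10%. The count rose to 21 without Arf6null replicate 1 and 20 without Arf6null replicate 2. The calls of Gzmk, Wls, H2-Eb1, BC023719 and H2-T3 held without any single library. Those of Areg, Adgrg1, Sv2c or Itgb8 were lost without Arf6null replicate 3 or Arf6wt replicates 1, 2 or 3, with adjusted p-values of 0.0562 to 0.185. With the title prefix as a covariate Wls, Areg, Adgrg1, Sv2c, Itgb8, BC023719 and H2-T3 lost their calls (adjusted p of 0.0526 to 0.213). The same 7 lost them with Y-linked reads as a covariate (0.0986 to 0.420), while Gzmk and H2-Eb1 kept theirs with both. Either covariate leaves 1 Arf6null library to set the genotype change. Gzmk and Eomes were among the markers that named the class. On mm10 the Gzmk span (chromosome 13, 113171608 to 113225908) contains Esm1 on the other strand, which was below the expression filter in these cells. Different clusters held most of the class in the pooled cells of the 2 genotypes. Clusters t3, t5 and t9 held 35.4, 29.7 and 17.0% of the Arf6null cells, and t1, t2 and t8 held 32.3, 28.9 and 18.7% of the Arf6wt cells. Clusters t1 and t8 drew 98.7 and 93.8% of their cells from Arf6wt replicate 3 and t2 drew 89.0% from Arf6wt replicate 1. Arf6null replicate 2 gave 90.4% of t5, and t3 and t9 drew at most 63.5% from 1 library. The leading genes of t2 included Trbc2, Klrd1, Tcf7, Cd160 and Trdc and no Cd3 or Cd8 gene. Tcf7 was also among those of t8. Whether such cells set the lower stem-like list was not tested. Arf6wt replicate 2 had 39 CD8 T-like cells, and the other libraries 211 to 664.

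T cell exhaustion genes were higher as a list in CD8 T-like cells, with 15 of 16 members positive, 0 passing over all genes (edgeR, 9 at an unadjusted p under 0.05) and 8 passing when adjusted over the list alone. Camera gave an adjusted p of 4.14e-13 (and adjusted p = 0.226 with an estimated correlation). Tox, the exhaustion transcription factor, was at 246 ± 46.5 against 59.2 ± 36.2 CPM (log2 change 2.18 ± 0.44, adjusted p = 0.0986), and the ectonucleotidase gene Entpd1 at 144 ± 36.2 against 42.8 ± 18.4 CPM. Pdcd1, the gene of the checkpoint receptor PD-1, was at 512 ± 98.8 against 169.9 ± 52.6 CPM and Eomes at 131 ± 18.2 against 53.3 ± 4.61 CPM. Stem-like or memory genes were lower as a list, with 12 of 12 members negative, 0 passing over all genes (11 at an unadjusted p under 0.05) and 9 passing when adjusted over the list alone (adjusted p = 3.29e-12, and adjusted p = 0.277 with an estimated correlation). Klf2, which maintains T cell quiescence and egress, was at 165 ± 27.1 against 429 ± 84.6 CPM, Tcf7, the gene of the memory factor TCF-1, at 39.5 ± 19.7 against 131 ± 82.0 CPM. Satb1 was at 93.3 against 304 ± 187 CPM and the homing receptor gene Ccr7 at 15.9 against 52.6 ± 44.7 CPM. Within the shared prefix Tox differed by 2.05, Pdcd1 by 1.78, Klf2 by −1.08 and Tcf7 by −2.85 on the log2 scale. Both calls held without any single library. Markers of naive or central memory T cells, another named class, were lower in 7 of 8 members in the same cells (adjusted p = 1.51e-05, and adjusted p = 0.287 with an estimated correlation), with Ccr7, Tcf7, Satb1 and Lef1 leading. The inhibitory receptor genes Lag3 (289 ± 164 against 93.2 ± 59.6 CPM) and Havcr2 (94.1 ± 35.2 against 73.4 ± 42.9 CPM), the granzyme gene Gzmb (1324 ± 449 against 2105 ± 684 CPM) and the interferon gamma gene Ifng (283 ± 212 against 264 ± 185 CPM) did not pass.

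**Figure D3:**
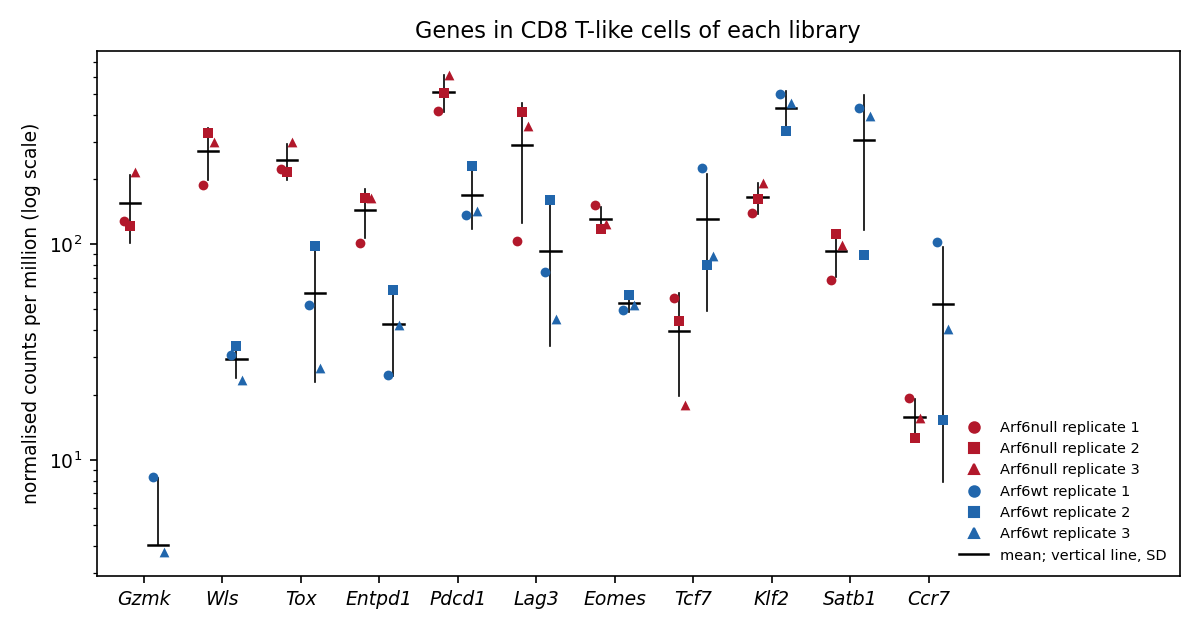
Normalised CPM (log scale) of 11 genes in the CD8 T-like cells of each library; points are libraries, horizontal bars group means and vertical lines the SD, and Gzmk in Arf6wt replicate 2, at 0, is not drawn. Gzmk, Wls, Tox, Entpd1, Pdcd1 and Eomes lie higher in all Arf6null libraries than in any Arf6wt library, and Klf2 and Tcf7 lower.

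A further 7 lists passed in CD8 T-like cells. Of the 10 splits of the libraries into 3 and 3, 3 gave at least 9 lists in these cells, the real one among them, with 11 in the highest other. Proliferation genes were higher in 25 of 25 members (adjusted p = 2.32e-06, and adjusted p = 0.715 with an estimated correlation), with Top2a at 527 ± 245 against 188 ± 83.1 CPM. Regulatory T cell function genes were higher in 10 of 11, Areg passing over all genes and 3 passing when adjusted over the list alone (adjusted p = 4.17e-05, and adjusted p = 0.310 with an estimated correlation). MHC class II genes were higher in 8 of 10, H2-Eb1 alone passing (adjusted p = 5.86e-07, and adjusted p = 0.114 with an estimated correlation), and checkpoint genes in 11 of 13 (adjusted p = 0.00214, and adjusted p = 0.277 with an estimated correlation). RNA from other cells may set the MHC class II list here. Type I interferon genes were lower in 18 of 19 members (adjusted p = 9.59e-05, and adjusted p = 0.715 with an estimated correlation). Among them the interferon-induced protease gene Usp18 was at 3.48 against 26.3 CPM and the interferon regulatory factor gene Irf7 at 23.6 against 68.9 CPM. NF-kB genes were lower in 15 of 17 (adjusted p = 0.000365, and adjusted p = 0.307 with an estimated correlation) and immediate early genes in 13 of 17 (adjusted p = 0.0194, and adjusted p = 0.715 with an estimated correlation). Macrophage markers were higher (adjusted p = 0.00102, and adjusted p = 0.307 with an estimated correlation) and neutrophil markers lower (adjusted p = 0.000226, and adjusted p = 0.287 with an estimated correlation) in the same cells. Group 2 innate lymphoid markers, Areg among them, were higher in 4 of 5 members (adjusted p = 2.41e-05, and adjusted p = 0.0676 with an estimated correlation) and regulatory T markers in 6 of 7 (adjusted p = 0.0473, and adjusted p = 0.287 with an estimated correlation). Of the markers of T cells, those of CD8 T cells were higher in 7 of 8 members (adjusted p = 4.05e-11, and adjusted p = 0.0669 with an estimated correlation) and the general ones in 11 of 13 (adjusted p = 0.0494, and adjusted p = 0.372 with an estimated correlation). The immediate early call ended without Arf6null replicate 1 or Arf6wt replicate 1 and the checkpoint call without Arf6null replicate 2 or Arf6wt replicate 1. The type I interferon call ended without Arf6wt replicate 1, and all of these had adjusted p-values of 0.0865 to 0.757. The checkpoint call also ended with Y-linked reads as a covariate (adjusted p = 0.158), and the checkpoint and immediate early calls with the title prefix (0.0834 and 0.905). Cytotoxic effector genes and interferon gamma response genes did not pass (adjusted p = 0.488 and 0.408).

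In CD4 T-like cells, tested in 3 Arf6null and 2 Arf6wt libraries, a single gene of 2639 passed, the uncertain feature Gm10260, and 97 had an unadjusted p under 0.05. Among the genes that did not pass Wls had the smallest p, at 137 ± 13.7 against 4.71 ± 6.66 CPM (log2 change 4.72 ± 0.86, adjusted p = 0.0760). The groups stood apart for 17.1% of genes, where chance gives 20%. Hypoxia and glycolysis genes were higher in 14 of 15 members (camera, adjusted p = 0.000436, and adjusted p = 0.833 with an estimated correlation), with the glycolytic enzyme gene Tpi1 at 430.0 against 166 CPM. That call ended without Arf6wt replicate 3 (adjusted p = 0.660), with the title prefix as a covariate (0.452) and with Y-linked reads as a covariate (0.346). Macrophage markers were higher in 4 of 4 members (adjusted p = 0.00338, and adjusted p = 0.267 with an estimated correlation) and CD8 T markers in 4 of 4 (adjusted p = 0.0129, and adjusted p = 0.324 with an estimated correlation) in the same cells. General T cell markers were higher in 12 of 13 (adjusted p = 0.0232, and adjusted p = 0.324 with an estimated correlation). The count of genes was 2 without Arf6null replicate 1 or Arf6null replicate 2 and 0 without Arf6null replicate 3, with 241 at an unadjusted p under 0.05 there. The count of lists was 3 without Arf6null replicate 1 or Arf6null replicate 2, 5 without Arf6wt replicate 1 and 0 without Arf6wt replicate 3. Regulatory T-like cells reached 20 cells in 2 Arf6null libraries and 1 Arf6wt library and were not tested. There Foxp3, their lineage factor, was at 336 and 349 against 305 CPM and the interleukin-2 receptor gene Il2ra at 875 and 602 against 663 CPM. Ctla4 was at 1293 and 2305 against 1350.5 CPM and Il10 at 15.99 and 246 against 156 CPM.

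In NK-like cells, tested in 3 Arf6null and 2 Arf6wt libraries, 3 of 7704 genes passed, 1 higher and 2 lower, with 454 at an unadjusted p under 0.05. H2-Eb1 was at 79.2 ± 13.8 against 3.72 ± 1.58 CPM (log2 change 4.39 ± 0.48, adjusted p = 0.0072), and BC023719 was at least 29.7-fold lower (adjusted p = 0.0262). H2-Eb1 and the MHC class II list may reflect RNA from other cells here too. In the Arf6null libraries H2-Eb1 was at 1.25 to 2.56% of its macrophage- or monocyte-like level. For H2-Aa, H2-Ab1 and Cd74 the median was 1.40 to 3.03%. The next genes were Vars, the valyl-tRNA synthetase (127 ± 22.3 against 19.4 ± 5.59 CPM, adjusted p = 0.0537), and Wls (429.9 ± 64.9 against 66.9 ± 3.94 CPM, adjusted p = 0.0671). The groups stood apart for 20.4% of genes, where chance gives 20%. Dissociation and immediate early genes were lower in 17 of 17 members, 3 passing when adjusted over the list alone (camera, adjusted p = 9.08e-09, and adjusted p = 0.460 with an estimated correlation). Among them the stress genes Ier3 and Atf3 were at 48.1 against 265 CPM and at 13.4 against 38.3 CPM. MHC class II genes were higher in 7 of 8 (adjusted p = 1.83e-07, and adjusted p = 0.229 with an estimated correlation) and proliferation genes in 12 of 13 (adjusted p = 0.0106, and adjusted p = 0.649 with an estimated correlation). T cell exhaustion genes were lower in 10 of 15 (adjusted p = 0.0209, and adjusted p = 0.460 with an estimated correlation). Whether they moved differently from those of CD8 T-like cells was not tested. Pooled over libraries, cluster t7 held 57.7% of the Arf6null cells, while t4 and t13 held 58.4 and 32.8% of the Arf6wt cells. Arf6wt replicate 3 gave 93.4% of t13, Arf6wt replicate 1 gave 55.8% of t4 and Arf6null replicate 3 gave 41.7% of t7.

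Immunosuppressive macrophage genes were lower in 8 of 9 members in NK-like cells (adjusted p = 0.0163, and adjusted p = 0.460 with an estimated correlation), among them Lgals3, the galectin-3 gene, at 141 against 883 CPM. NF-kB genes were lower in 13 of 17 (adjusted p = 0.04996, and adjusted p = 0.649 with an estimated correlation). Neutrophil markers were lower in 3 of 3 members (adjusted p = 0.00765, and adjusted p = 0.774 with an estimated correlation) in the same cells. Without Arf6null replicate 3 the count of genes was 0, with 502 at an unadjusted p under 0.05, and H2-Eb1 and BC023719 had adjusted p-values of 0.0554 and 0.0709. BC023719 also lost its call without Arf6null replicate 1 (adjusted p = 0.0587) or Arf6null replicate 2 (adjusted p = 0.0511). Without Arf6wt replicate 1 the count was 13. The exhaustion, immunosuppressive, proliferation and NF-kB calls ended without Arf6null replicate 1 or Arf6null replicate 3. Some of them also ended without Arf6wt replicate 1 or Arf6wt replicate 3, and the adjusted p-values were 0.0594 to 0.543. The number of lists called was 3 without Arf6null replicate 1 or Arf6null replicate 3, of which 2 were among the 6, and 10 without Arf6null replicate 2, with all 6 among them. Y-linked reads as a covariate ended the calls of H2-Eb1 and BC023719 (adjusted p of 0.0913 to 0.391), the title prefix as a covariate the immunosuppressive call (0.1297) and the stricter cell filter the NF-kB call (0.0531).

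In macrophage- or monocyte-like cells, the largest class, 10 of 13890 genes passed, 5 higher and 5 lower. There were 1518 at an unadjusted p under 0.05, and the groups stood apart for 16.8% of genes, where chance gives 10%. Ifi44l rose to 82.4 ± 79.1 from 0.0141 CPM (log2 change 12.61 ± 1.24, adjusted p = 0.0179), Apol7c to 35.9 ± 0.996 from 0.138 CPM (8.35 ± 0.70, adjusted p = 0.00678) and H2-Eb1 to 4611 ± 2961 from 62.2 ± 11.1 CPM (6.21 ± 0.62, adjusted p = 0.0183). Vill fell to 0.0414 from 24.2 ± 13.3 CPM (adjusted p = 0.00612) and BC023719 to 0.00638 from 22.7 ± 4.38 CPM (adjusted p = 0.00132). All of these named genes are among the 14 that stood 10-fold apart over all cells. The genes often used to describe macrophage states did not pass. Arg1, the arginase gene, was at 209 ± 134 against 129.9 ± 120.4 CPM. Nos2, the inducible nitric oxide synthase gene, was at 38.0 ± 53.9 against 267 ± 214 CPM (log2 change −2.81, adjusted p = 0.467, and −6.41 within the shared prefix). Cd274, the PD-L1 gene, was at 58.9 ± 22.1 against 152 ± 17.3 CPM (−1.37 ± 0.34, adjusted p = 0.291, and −1.21 within the prefix). The chemokine genes Cxcl9 (256 ± 196 against 159 ± 168 CPM) and Cxcl10 (532 ± 503 against 632 ± 253 CPM), the mannose receptor gene Mrc1 (1115 ± 704 against 902 ± 549.7 CPM), Spp1 (686 ± 224 against 1083 ± 1078 CPM) and Il10 (25.2 ± 4.36 against 28.9 ± 12.7 CPM) overlapped between genotypes or varied as much within them. Tgfb1 (328 ± 73.1 against 347 ± 94.0 CPM), Vegfa (96.0 ± 18.6 against 124 ± 56.0 CPM) and Ifngr1 (456 ± 199.8 against 651 ± 166 CPM) had adjusted p-values of 0.951, 0.743 and 0.699.

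Proliferation genes were higher as a list in macrophage- or monocyte-like cells, with 22 of 25 members positive, 0 passing over all genes (edgeR, 8 at an unadjusted p under 0.05) and 6 passing when adjusted over the list alone (camera, adjusted p = 1.78e-05, and adjusted p = 0.667 with an estimated correlation). The replication licensing gene Mcm3 was at 34.2 ± 5.37 against 13.3 ± 2.2 CPM. NF-kB genes were lower as a list, with 16 of 17 members negative and 0 passing when adjusted over the list alone in edgeR, 6 of them at an unadjusted p under 0.05 (adjusted p = 1.78e-05, and adjusted p = 0.708 with an estimated correlation), with Sod2 at 160.4 ± 32.3 against 482 ± 242 CPM. Proinflammatory genes were lower as a list, with 13 of 18 members negative and 3 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00210, and adjusted p = 0.708 with an estimated correlation). There Il1a was at 113 ± 17.7 against 361 ± 124 CPM and Acod1 at 8.66 against 63.4 ± 58.5 CPM. Hypoxia genes were lower in 22 of 25 (adjusted p = 0.0347, and adjusted p = 0.997 with an estimated correlation), with Hilpda, a lipid droplet gene, at 355 ± 218 against 975 ± 522 CPM. In the same cells neutrophil markers, Acod1 among them, were lower in 8 of 10 members (adjusted p = 0.000960, and adjusted p = 0.658 with an estimated correlation) and monocyte markers in 10 of 11 (adjusted p = 0.00462, and adjusted p = 0.695 with an estimated correlation). Macrophage markers were higher in 11 of 14 (adjusted p = 0.00231, and adjusted p = 0.438 with an estimated correlation). B cell markers were higher in 7 of 8 (adjusted p = 0.00317, and adjusted p = 0.438 with an estimated correlation) and mature dendritic markers in 6 of 10 (adjusted p = 0.00317, and adjusted p = 0.658 with an estimated correlation). The immunosuppressive macrophage and interferon gamma response lists did not pass (adjusted p = 0.712 and 0.990). Of the 10 splits of the libraries into 3 and 3, 7 gave at least 4 lists, the real one among them, with 13 in the highest other. The number of lists thus does not set genotype apart here. Pooled over libraries, clusters m0, m1, m5 and m6 held 24.6, 20.3, 14.1 and 11.96% of the Arf6null cells, and m4, m3, m9 and m19 held 30.3, 25.0, 16.6 and 11.8% of the Arf6wt cells. Clusters m0, m1 and m6 drew 81.9, 84.2 and 83.7% of their cells from Arf6null replicates 3, 1 and 2. Clusters m4 and m19 drew 97.3 and 90.4% from Arf6wt replicates 3 and 1, and m5, m3 and m9 at most 61.8% from 1 library. The count of genes was 6, 3 and 5 without Arf6wt replicates 1, 2 and 3. There Ifi44l, H2-Eb1 or, without replicate 2, Apol7c lost their calls at adjusted p-values of 0.0768 to 0.193. The hypoxia call ended without Arf6null replicate 1, Arf6null replicate 3, Arf6wt replicate 1 or Arf6wt replicate 2. The proinflammatory call ended without Arf6null replicate 2, and the adjusted p-values were 0.0544 to 0.711. Without Arf6null replicate 3 the number of lists was 10 in place of 4. With the title prefix as a covariate the NF-kB and proinflammatory calls ended (adjusted p of 0.109 to 0.772), and with Y-linked reads as a covariate those of all 5 genes named (0.0900 to 0.107).

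In neutrophil-like cells 6 of 8329 genes passed, 3 higher and 3 lower. There were 761 at an unadjusted p under 0.05, and the groups stood apart for 14.6% of genes, where chance gives 10%. The cathepsin inhibitor genes Csta3 (2.63 ± 1.41 against 54.6 ± 19.6 CPM, log2 change −4.22 ± 0.49, adjusted p = 0.0220) and Cstdc6 (0.185 against 72.7 ± 51.8 CPM, adjusted p = 0.0220) fell, and BC023719 was at least 59.0-fold lower (adjusted p = 0.0423). The MHC genes H2-Eb1 (198 ± 80.5 against 9.02 ± 4.44 CPM, adjusted p = 0.0220) and H2-Q10 (461 ± 268 against 16.2 ± 9.21 CPM, adjusted p = 0.0452) rose, and Skint3 was at least 113-fold higher (adjusted p = 0.0220). Each of these belongs to a multigene family or overlaps one and is uncertain. Hypoxia genes were lower in 19 of 23 members (camera, adjusted p = 0.00916, and adjusted p = 0.977 with an estimated correlation). Among them Ldha, the lactate dehydrogenase gene, was at 420.1 ± 133 against 994 ± 378 CPM and the glucose transporter gene Slc2a1 at 177 against 421 CPM. NF-kB genes were lower in 15 of 17 (adjusted p = 0.0197, and adjusted p = 0.977 with an estimated correlation) and proinflammatory genes in 10 of 16, 2 passing when adjusted over the list alone (adjusted p = 0.0428, and adjusted p = 0.977 with an estimated correlation). MHC class II genes were higher in 9 of 10 (adjusted p = 0.00916, and adjusted p = 0.977 with an estimated correlation), a call that ended without H2-Eb1 in the list (adjusted p = 0.334), as did the proinflammatory call (0.0535). TGF beta genes were higher in 9 of 10 (adjusted p = 0.0197, and adjusted p = 0.977 with an estimated correlation). Macrophage markers were higher in 11 of 14 (adjusted p = 7.1e-06, and adjusted p = 0.766 with an estimated correlation) in the same cells. The costimulatory gene Cd86 was at 18.8 ± 5.54 against 64.2 ± 13.2 CPM (adjusted p = 0.159).

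The neutrophil-like gene count was 68 without Arf6null replicate 2, 0 without Arf6null replicate 3, 2 without Arf6wt replicate 1, 0 without Arf6wt replicate 2 and 10 without Arf6wt replicate 3. At the counts of 0 there were 628 and 548 genes at an unadjusted p under 0.05. The stricter cell filter ended the calls of BC023719, Csta3 and H2-Q10 (adjusted p = 0.0514), and DESeq2 size factors in edgeR that of H2-Q10 (0.0502). At Leiden resolution 2 the count was 7, of which 3 were among the 6, and Csta3 and H2-Q10 lost their calls (0.0697 and 0.0718), while Skint3 was not tested there. The class then took in a cluster of 339 cells led by Ctsk, Atp6v0d2 and Mmp9, genes of osteoclasts, of which 74, 18 and 239 were in the Arf6null libraries. Each of Skint3, H2-Q10, H2-Eb1, BC023719, Cstdc6 and Csta3 lost its call without Arf6null replicate 3 or Arf6wt replicate 2. Some lost it without Arf6null replicate 1, Arf6wt replicate 1 or Arf6wt replicate 3, all at adjusted p-values of 0.0675 to 0.247. The 5 lists became 3 without Arf6null replicate 2, 8 without Arf6null replicate 3 and 2 without Arf6wt replicate 1. Each call ended without at least 1 library, at adjusted p-values of 0.0557 to 0.608. Of the 10 splits of the libraries into 3 and 3, 9 gave at least 5 lists, the real one among them, with 11 in the highest other. The number of lists thus does not set genotype apart here. All 6 genes lost their calls with the title prefix (adjusted p of 0.410 to 0.523) or Y-linked reads (0.354 to 0.596) as a covariate. So did the NF-kB and proinflammatory lists with the prefix (0.0582 to 0.255), and with Y-linked reads these and the MHC class II and hypoxia lists (0.131 to 0.920). Pooled over libraries, clusters m8 and m13 held 51.2 and 40.7% of the Arf6null neutrophil-like cells, and m2, m10 and m11 held 47.4, 24.2 and 19.7% of the Arf6wt cells. Such shares can follow single libraries. With doublets kept, the cluster led by Retnlg held 17, 1369 and 12 Arf6null cells and that led by Gm19951 525, 10 and 566. Those led by Asprv1 with Mrgpra2b, by Cxcl3 and by Asprv1 with Csf3r held 532, 2712 and 30, 1542, 55 and 80, and 855, 450 and 5 Arf6wt cells.

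Dendritic-like cells reached 20 cells in 2 libraries of each genotype. There 2 of 8882 genes passed, both lower, BC023719 (at least 121-fold, adjusted p = 0.0175) and Gm10260. There were 372 at an unadjusted p under 0.05, and the groups stood apart for 29.2% of genes, where chance gives 33.3%. Wls was at 176 ± 15.97 against 12.2 ± 3.92 CPM (log2 change 3.81, adjusted p = 0.0917). Proliferation genes were higher in 22 of 24 members, 3 passing when adjusted over the list alone (camera, adjusted p = 3.34e-14, and adjusted p = 0.883 with an estimated correlation). Immunosuppressive macrophage genes were higher in 12 of 17, 5 passing when adjusted over the list alone (adjusted p = 3.82e-08, and adjusted p = 0.883 with an estimated correlation). The complement gene C1qa, a macrophage marker, was at 257 ± 147 against 16.6 CPM in the same cells, where macrophage markers were higher in 12 of 12 members (adjusted p = 2.35e-21, and adjusted p = 0.469 with an estimated correlation). Regulatory T markers were higher in 6 of 7 (adjusted p = 0.00556, and adjusted p = 0.684 with an estimated correlation) and endothelial markers lower in 3 of 3 (adjusted p = 0.000295, and adjusted p = 0.469 with an estimated correlation). Among the class's own lists, conventional dendritic cell 1 markers were higher in 8 of 9 (adjusted p = 0.000754, and adjusted p = 0.469 with an estimated correlation) and mature dendritic markers in 6 of 10 (adjusted p = 0.000295, and adjusted p = 0.684 with an estimated correlation). Cluster m16, led by Plet1, Ccl17 and Xcr1, held 72.8% of the Arf6null and 85.0% of the Arf6wt dendritic-like cells, and m24, led by Ccr7, Ccl22 and Fscn1, 27.2 and 15.04%. Arf6null replicate 1 gave 64.6% of the cells of m16 and 81.8% of those of m24. Interferon gamma response genes were lower in 16 of 24 (adjusted p = 0.00902, and adjusted p = 0.883 with an estimated correlation), and unfolded protein response genes were higher in 11 of 16 (adjusted p = 0.0306, and adjusted p = 0.894 with an estimated correlation). The gene count was 0 without Arf6null replicate 1 (119 at an unadjusted p under 0.05), 29 without Arf6null replicate 3, 209 without Arf6wt replicate 1 and 1 without Arf6wt replicate 3. BC023719 had an adjusted p of 0.271 without Arf6null replicate 1 and 0.0595 without Arf6wt replicate 3. The 4 lists became 8 without Arf6null replicate 3, 7 without Arf6wt replicate 1 and 9 without Arf6wt replicate 3. The interferon gamma call ended without Arf6null replicate 1 or Arf6wt replicate 3. The unfolded protein call ended without Arf6null replicate 3 or Arf6wt replicate 3, both at adjusted p-values of 0.0833 to 0.904, and also with Y-linked reads as a covariate (adjusted p = 0.372).

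The make-up of the retained cells varied widely between tumours of 1 genotype. Macrophage- or monocyte-like cells were 62.6 ± 5.01% of retained cells in Arf6null and 45.9 ± 17.6% in Arf6wt (exact p = 0.3). Neutrophil-like cells were 11.5 ± 7.53 against 37.2 ± 25.0% (exact p = 0.2) and CD8 T-like cells 3.92 ± 1.66 against 6.28 ± 5.44% (exact p = 0.6). Dendritic-like cells were 4.84 ± 5.26 against 0.602 ± 0.289% (exact p = 0.4), NK-like cells 1.46 ± 1.03 against 1.83 ± 1.40% (exact p = 0.9) and regulatory T-like cells 1.41 ± 1.90 against 0.843 ± 1.13% (exact p = 0.7). Of 13 classes 0 passed (edgeR quasi-likelihood test on cell counts), and 2 had an unadjusted p under 0.05. These were gamma delta T-like cells, at 0.205 ± 0.192 against 0.0158 ± 0.0146%, and mast or basophil-like cells, at 0.866 ± 1.10 against 0.0659 ± 0.0703% (both adjusted p = 0.247 and exact p = 0.1, the smallest possible). Within the shared prefix neutrophil-like cells were 7.16% of the Arf6null library and 50.8% on average in the Arf6wt libraries, and macrophage- or monocyte-like cells 68.3 against 35.7%. Cells in unnamed clusters, kept out by a naming rule set after the data were seen, were 9.69 ± 1.56 against 4.71 ± 3.13% (exact p = 0.2). The CD45 sort and the dissociation can set all of these shares, and of 46 clusters 20 drew over 80% of their cells from a single library.

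**Figure D4:**
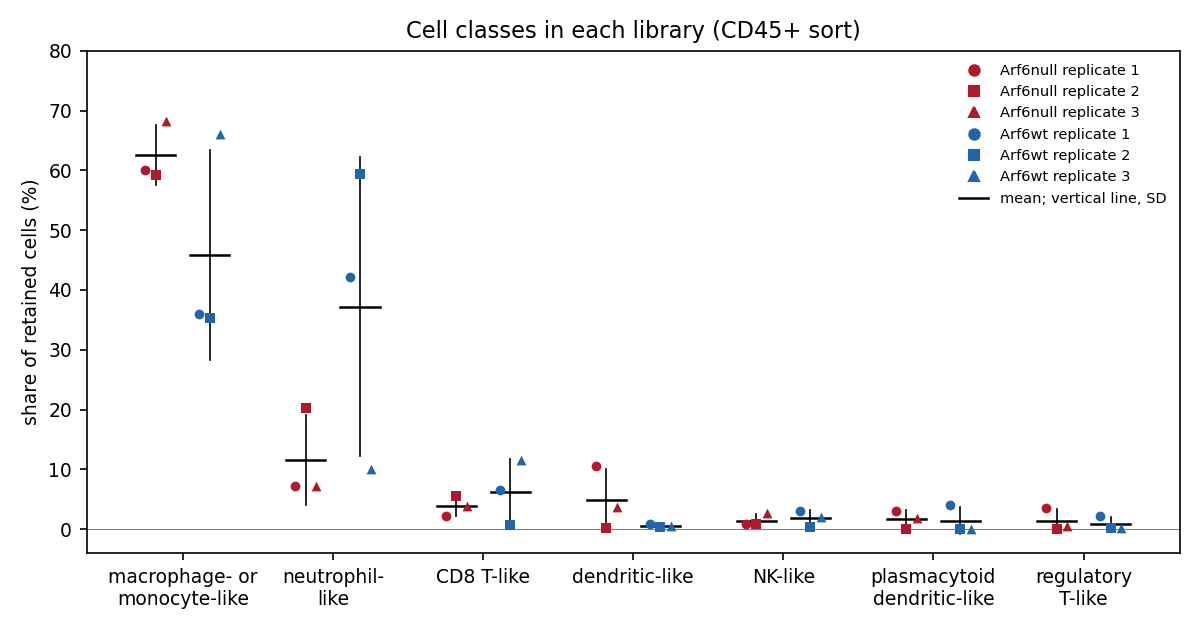
Share of retained cells (%) of 7 classes in each library; points are libraries, horizontal bars group means and vertical lines the SD. Neutrophil-like cells averaged 11.5% in Arf6null and 37.2% in Arf6wt, and the libraries of the genotypes overlap in each class drawn.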

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

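The tests of a wrong label and of RNA from immune cells, and the choice of the Ptprc-low cluster, came only after the result was seen. The genotype effect on Arf6 differed between the Ptprc-low cells and the immune classes, tested as an interaction with the library as a block in edgeR. The log2 change in the Ptprc-low cells lay −5.87 ± 0.32 from that in macrophage- or monocyte-like cells (adjusted p = 0.00113), −6.38 ± 0.35 from that in CD8 T-like cells (adjusted p = 1.54e-05) and −5.82 ± 0.42 from that in neutrophil-like cells (adjusted p = 0.000132), and Arf6 was the gene of smallest p in each of these tests. In all 3 Arf6null libraries Arf6 in the Ptprc-low cells was lower than in any Arf6wt library.

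A wrong genotype label on a library is argued against, since the highest Arf6null level was 0.0207 of the lowest Arf6wt level. RNA of immune cells is a candidate source of the few Arf6 UMIs left in the Arf6null libraries: 19 were counted, 0.790 of the 24.1 that the Ptprc UMIs of the same cells and the ratio of Arf6 to Ptprc in macrophage- or monocyte-like cells would give. Incomplete deletion in some cells would also leave such UMIs and was not tested. The hypothesis that the Ptprc-low cells are the cells that lost Arf6 rests on these libraries alone. Their kind stays open, since pigment cell markers were near the floor in them. At Leiden resolution 2 their best list was that of fibroblasts, with 8 markers detected and 0 among the 10 leading genes.

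Reads of the Y-linked gene Ddx3y, which served only to set a covariate, came to 6153 UMIs in Arf6null replicate 2 and 5714 UMIs in Arf6null replicate 3. Arf6null replicate 1 held 4 such UMIs and the 3 Arf6wt libraries 0, and reads above the level of the control genotype are what drew attention to this gene.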

How the results depend on the processing

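The covariate for Y-linked reads, the MHC class II list without H2-Eb1 and all alternatives for the Ptprc-low cells were chosen only after the data were seen. No paired analysis was possible because the design text calls the tumours of the genotypes matched without saying which go together, and the replicate numbers only follow the order of the records. Among called genes 336 values kept direction and threshold under the alternatives and 160 kept direction alone, and among called lists 269 kept both, 107 direction alone and 1 neither. That one was the NF-kB list in NK-like cells, which pointed upward without Arf6wt replicate 1, where its adjusted p was 0.543 in a range of 8.58e-06 to 0.543 over the left-out libraries. DESeq2 called 762 genes over all cells, 71 in CD8 T-like, 25 in NK-like, 337 in macrophage- or monocyte-like, 25 in dendritic-like, 98 in neutrophil-like and 96 in Ptprc-low cells. With no filter on low counts, which tests more genes, edgeR called 32 over all cells, 259 in CD8 T-like, 13 in CD4 T-like, 93 in NK-like, 43 in macrophage- or monocyte-like, 101 in dendritic-like, 334 in neutrophil-like and 29 in Ptprc-low cells. With the title prefix as a covariate it called 4 genes over all cells, 5 in CD8 T-like, 97 in NK-like and 0 in CD4 T-like, neutrophil-like and Ptprc-low cells (157, 721 and 540 at an unadjusted p under 0.05), and 9 lists in macrophage- or monocyte-like cells. Of those 9 lists 2 were among the 4 called without the covariate. In NK-like and CD4 T-like cells, without Arf6wt replicate 2, the genotype change then rests on Arf6null replicate 3 against Arf6wt replicate 1 alone. The stricter cell filter gave 2 genes in CD4 T-like and 3 in neutrophil-like cells, and keeping doublets gave 15 in NK-like and 4 in dendritic-like cells. With Y-linked reads as a covariate edgeR called 0 genes over all cells and in NK-like, macrophage- or monocyte-like, neutrophil-like and Ptprc-low cells (1365, 262, 1254, 654 and 668 at an unadjusted p under 0.05). There were 2 in CD8 T-like and 40 in dendritic-like cells, and 12 lists over all cells, 0 in CD4 T-like, 10 in NK-like, 12 in macrophage- or monocyte-like and 9 in dendritic-like cells. Without H2-Eb1 in the MHC class II list 3 lists passed in neutrophil-like cells. An estimated correlation left 0 lists in each of the 7 tested sets of cells. Covariates leave fewer degrees of freedom, and beyond the fewer samples or more genes of an alternative the cause was not tested.

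Leaving out 1 library gave 3 to 30 genes over all cells, 9 to 21 in CD8 T-like, 0 to 2 in CD4 T-like, 0 to 13 in NK-like, 3 to 14 in macrophage- or monocyte-like, 0 to 209 in dendritic-like, 0 to 68 in neutrophil-like and 1 to 11 in Ptprc-low cells. The lists numbered 5 to 10 over all cells, 7 to 12 in CD8 T-like, 0 to 5 in CD4 T-like, 3 to 10 in NK-like, 4 to 10 in macrophage- or monocyte-like, 3 to 9 in dendritic-like and 2 to 8 in neutrophil-like cells. The number of classes whose share passed stayed at 0, and Arf6 over all cells ranged from −0.75 to −0.29. Where this left a genotype with 1 library, that library was assumed to vary like the others. Simulated 4-fold changes were recovered for 44% of genes in dendritic-like cells (2 libraries against 2), 57% over all cells and 85% in CD8 T-like cells. The simulation left out differences in spread between genes, so real recovery can be lower. Recovery did not follow the number of cells, so depth was not shown to be the limit.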

Other observations

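The tests of a background variant, of a batch in the genes 10-fold apart, of RNA from other cells, of the sex of the animals and of the Ptprc-low lists were chosen only after the results were seen. In the Ptprc-low cells, MHC class II genes were higher in 7 of 9 members (camera, adjusted p = 1.64e-10, and adjusted p = 0.397 with an estimated correlation), with H2-Eb1 the one past the threshold, and Lyz2 was at 134 ± 101 against 26.4 ± 19.6 CPM (exact p = 0.3) and Ptprc at 14.4 ± 6.26 against 9.52 ± 3.45 CPM (exact p = 0.2). NF-kB genes were lower in 14 of 17 members (adjusted p = 0.000121, and adjusted p = 0.294 with an estimated correlation), immediate early genes in 18 of 18 (adjusted p = 0.000131, and adjusted p = 0.685 with an estimated correlation) and type I interferon genes in 15 of 18 (adjusted p = 0.0208, and adjusted p = 0.784 with an estimated correlation). Esm1, a proteoglycan gene of endothelium and some tumours, was at 75.2 CPM in Arf6null and 0 in Arf6wt (adjusted p = 0.0576). A second unnamed cluster, led by Crabp1, Nefl, Cryab, Krt18 and Gap43, held 3.95, 2.51 and 3.095% of the Arf6null and 1.24, 1.06 and 1.70% of the Arf6wt cells, with Arf6 at 5.78 ± 7.16 against 68.3 ± 20.9 CPM (exact p = 0.1, the smallest that 3 against 3 libraries allow).

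An unnamed cluster led by osteoclast genes (Ctsk, Atp6v0d2 and Mmp9) together with cycling genes held 2.501, 3.31 and 3.76% of the Arf6null and 0.332, 0.0747 and 0.350% of the Arf6wt cells. At Leiden resolution 2 the osteoclast genes, with the neutrophil genes Camp and Ngp, led a cluster of 74, 18 and 239 Arf6null and 1, 3 and 4 Arf6wt cells, and cycling genes a macrophage-like one of 190, 221 and 84 against 29, 2 and 16 cells. Over all cells mast cell or basophil markers were higher in 9 of 11 members (camera, adjusted p = 0.0108, and adjusted p = 0.751 with an estimated correlation) and endothelial markers lower in 8 of 8 (adjusted p = 0.0112, and adjusted p = 0.751 with an estimated correlation), and the sort should remove endothelial cells. Wls had a log2 change of 3.25 in CD8 T-like, 4.72 in CD4 T-like, 2.68 in NK-like and 3.81 in dendritic-like cells, and passed in CD8 T-like cells alone.

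The 14 genes at least 10-fold apart between the genotypes differed so in 49 of 51 pairs of gene and class, and in 13 of 13, or 100%, of those that the choice of genes leaves free with the gene at 0.5 of its level over all cells or more, which cover 6 of the genes. A title batch as the whole cause of such gaps is argued against by 68 genes chosen by the same gap in the libraries of the other prefixes. Of these 19 differed the same way by genotype within the shared prefix and 0 the other way, against at most 1 with either Arf6wt library set against the rest. The 14 genes are among the 19 by the way they were chosen, so that overlap tests nothing. H2-Eb1 in CD8 T-like and NK-like cells may be RNA from other cells, as its level relative to macrophage- or monocyte-like cells was 1.07 times that of H2-Aa, H2-Ab1 and Cd74 in the median. That source is argued against for BC023719 and Gm10260, whose lowest such ratio was 108. A difference in strain background at several loci, the MHC among them, which the labels do not describe, stays open as a hypothesis and cannot be told apart from genotype for these genes.

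In CD8 T-like cells the difference between the medians of the exhaustion and stem-like lists within the shared prefix was 0.993 of that over all libraries, and in the libraries without Y-linked reads 0.540 of it. Each rests on 1 Arf6null library. Against single Arf6wt libraries the first ranged from 0.497 to 1.80 and the second from 0.0866 to 1.24, while libraries of 1 genotype differed by up to 2.16. These ranges and the 0.540 use log2 of CPM plus 10, where the difference over all libraries was 1.97. The 0.993 comes from the log2 values of the gene tests (2.51 against 2.53), so its range is on another scale. A title batch and the sex of the animals both stay open. After thinning to 1500 UMIs per cell and 34 cells per library, with 41, 25 and 29 shallower cells left out of the Arf6null and 17, 5 and 43 out of the Arf6wt libraries, the difference was 2.32 ± 0.383 against 1.97 unthinned, a ratio of 1.18, which argues against depth. RNA of other cells and a difference in background stay open, and so does a biological effect of tumour Arf6. The hypothesis that CD8 T cells of these Arf6null tumours are further along toward exhaustion therefore stays one.

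With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, gave as many in each of the sets tested: 21 over all cells against 1 in the highest other split, 13 against 0 in CD8 T-like, 10 against 1 in macrophage- or monocyte-like, 6 against 2 in neutrophil-like and 6 against 1 in Ptprc-low cells. For lists, 7 of the splits gave at least the 7 over all cells (highest other 11), 3 the 9 in CD8 T-like (11), 7 the 4 in macrophage- or monocyte-like (13) and 9 the 5 in neutrophil-like cells (11). For shares the real count was 0, which each of the 10 splits reaches by construction, so nothing was tested there (highest other 3). The split that sets the 19237 libraries against the rest gave as many lists as the real one or more in 3 of these sets: 9 over all cells, 9 in macrophage- or monocyte-like and 7 in neutrophil-like cells. With the title prefix as a covariate the real split gave 6, 9 and 5 lists there, of which 4, 2 and 3 were among the calls made without it.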
